A study of Mus musculus with 2 samples.

How the data were processed

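Messenger RNA of sorted mouse CD4+ T cells was measured on Affymetrix Mouse Genome 430 arrays, which carry several short probes per transcript, grouped into probe sets. Per the labels, the cells came from DEREG mice, which express green fluorescent protein (GFP) under the Foxp3 promoter. CD4+ T cells were enriched by negative selection and sorted into GFP-positive and GFP-negative cells at a stated purity of more than 99%. Total RNA was extracted with Trizol and 6 µg were turned into biotin-labelled cRNA, per the labels' protocols. The design holds 2 arrays, 1 per group, and each was placed in its group by its title. The organ, the age and number of the mice and any treatment are not given in the sources used here.

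The deposited values are 1 intensity per probe set and array, on a linear scale, summarised by the authors with MAS5, per the submitters' processing notes. The software version, the background settings and the detection calls are not given in the sources used here. The values show that the arrays had been scaled to each other before deposit, since the 2% trimmed mean over all probe sets was 150.0 on both. No further scaling, background correction or normalization was applied in the main analysis.

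Of the 45101 probe sets, 34958 were paired with 1 gene symbol by the platform annotation, 932 with several and 9211 with none. Probe sets with several symbols or none entered no gene comparison, nor did the 64 control probe sets. Symbols were updated through gene identifiers where these matched the reference gene table, which 34754 probe sets did. That step altered 0 symbols. A gene was represented by the probe set with the highest mean log2 signal over both arrays, which gave 18193 genes.

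Without detection calls, a signal floor was taken from genes whose expression is restricted to other tissues, such as liver, muscle, pancreas, neurons and germ cells. The floor was the 90th percentile of their signals over both arrays, from 104 probe sets of 64 genes out of 70 listed, and came to 62.05. Signals under the floor were raised to it before log2 was taken. A gene entered if at least 1 of its signals lay above the floor. Because genes are represented by their brightest probe set, 16 of the 64 tissue-restricted background genes passed this rule. The median signal of these 64 genes was 32.15 on the GFP-positive and 14.2 on the GFP-negative array. For a gene with only 1 signal above it, the fold is a lower bound and is written as at least N-fold. All differences are log2 GFP-positive minus log2 GFP-negative.

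With 1 array per group there is no residual spread, so no test was run and no p-value or standard error is given. Genes were counted past a fixed fold of 2. The arrays' number limits the precision. As a yardstick of technical scatter within these arrays, the log2 differences of probe sets of the same gene had a standard deviation of 0.40, from 8139 probe sets of 3198 genes above the floor on both arrays. That value holds no variation between animals, sorts or hybridisations.

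For gene groups, 23 lists were fixed before the data were examined: genes known as high in regulatory T cells, genes lower in them, naive and recirculating T cells, activated and effector T cells, cytokines, T helper lineage transcription factors, chemokine receptors and homing molecules, the TNF receptor family, co-stimulatory and co-inhibitory receptors, suppressor effector molecules, IL-2 and STAT5 signalling, T cell receptor signalling, immediate early genes, heat shock and stress, proliferation, interferon-stimulated genes, glycolysis, ribosomal proteins, markers of B cells, of myeloid and dendritic cells, of CD8 T and NK cells and of erythroid cells and platelets, and sex-linked genes. The median difference of each list was placed among 10000 random lists of the same size, drawn for each member from the 100 genes nearest to it in mean signal, with a fixed seed. This percentile describes these arrays and is not a test. Some lists share members, and the lists that share members with the regulatory T cell list were also summarised without them, an alternative chosen after seeing the data.

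The named genes followed a rule written before the data were examined. Foxp3, Il2ra, Ctla4, Tnfrsf18, Ikzf2 and Il7r were always named. By size, the rule took up to 8 genes per direction with the largest difference among genes above the floor on both arrays, and up to 5 per direction with the largest lower bound among genes above it on 1 array. From each list it took up to 4 members above the floor with the largest absolute difference and, where no member passed 2-fold, the 2 members with the highest mean signal. All measured sex-linked genes were also included. Where probe sets of a named gene disagree in direction by more than 1 log2 unit, the disagreement is given. Such disagreement alone did not lead to a gene being named. Genes named outside the rule are said to be so.

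The steps were tested on simulated data made from the GFP-positive against GFP-negative comparison, with noise of 0.4 log2 and 9315 genes. The noise was the same at every signal level. Changed genes and the shifted list were drawn only from genes above the floor on both arrays, with a mean signal more than 4-fold above it. Recovery of differences near the floor, and larger scatter there, were not simulated. Of 100 genes given a true 4-fold difference, 100% passed 2-fold in the true direction, and 52% of 100 genes with a true 2-fold difference did. Of 9090 unchanged genes, 97 passed 2-fold, or 1.07%. A list shifted by 0.5 log2 had a median of 0.48 and lay at percentile 100, and 8 of 100 unshifted lists lay outside percentiles 2.5 to 97.5.

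The alternatives were scaling to the same trimmed mean or the same median, quantile normalization, loess of the difference on the mean signal, a floor at the median probe set, a doubled floor, no floor, the mean over all probe sets of a gene, leaving out probe sets that can match several transcripts, fold thresholds of 1.5 and 3, and means in place of medians for lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. No genome build was used, so no coordinates are given.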

Results

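CD4+ T cells of DEREG mice, in which the Foxp3 promoter drives GFP, were sorted into GFP-positive and GFP-negative cells, and each population was profiled on 1 microarray. Foxp3 is the transcription factor that defines regulatory T cells, so the comparison asks how the regulatory T cells of these mice differ in gene expression from their other CD4+ T cells. There are no replicates, and every difference below is between these 2 arrays. The median signal over all 45101 probe sets was 46.9 on the GFP-positive array and 40.8 on the GFP-negative array. Signals above the floor of 62.05 were found for 18897 probe sets (41.9%) and 17629 probe sets (39.1%), respectively. The 3′ to 5′ signal ratio, which is higher where RNA is degraded or incompletely copied, was higher on the GFP-positive array. For Actb it was 5.30 in GFP-positive and 3.57 in GFP-negative cells, and for Gapdh 9.27 and 6.24. Hybridisation controls, added to each sample independently of its RNA, gave higher signals on the GFP-positive array for 17 of 18 probe sets, with a median of 1.23-fold.

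GFP-positive cells had higher signals for Foxp3 and for most genes known as high in regulatory T cells, among them Gpr83, Ecm1, Plagl1, Tnfrsf18 and Nt5e. GFP-negative cells had higher signals for Cxcr5, the chemokine receptor for B cell follicles, for the transcription factors Tox2 and Eomes, and for the cytokine genes Ifng and Tnf. The Tnf signal in GFP-negative cells was at a level that some tissue-restricted background genes also reached. Most other genes differed little. Of 10343 genes above the floor on at least 1 array, 181 were at least 2-fold higher in GFP-positive cells and 178 at least 2-fold lower, together 3.47%, and 83.2% lay within 1.5-fold. The median difference over these genes was −0.01 log2, and across the 8229 genes above the floor on both arrays, which are not independent replicates, the log2 signals correlated with r = 0.965. Of the 181 higher genes, 66 are lower bounds because the GFP-negative signal was below the floor, as are 65 of the 178 lower genes. The counts depend on the floor: with the floor doubled they were 57 and 68, and without a floor 3305 and 2420.

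**Figure D1:**
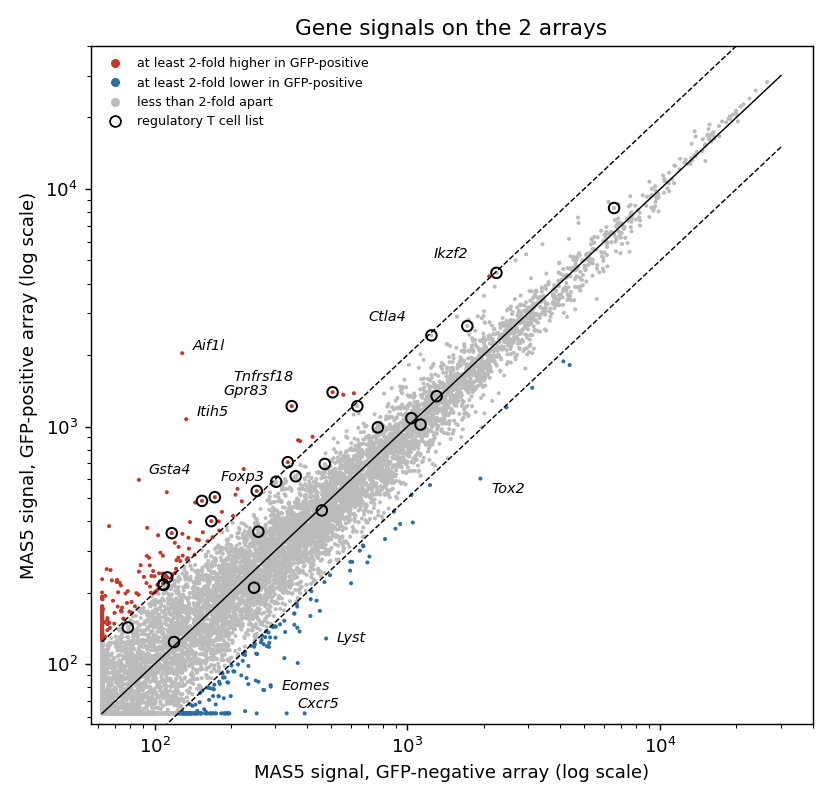
MAS5 signals of genes on the GFP-negative (x axis) and GFP-positive array (y axis), both in log scale, with signals below the floor of 62.05 drawn at the floor, a solid line of equal signal and dashed lines at 2-fold. The 181 genes at least 2-fold higher in GFP-positive cells are red, the 178 lower genes blue, and open circles mark the 28 genes of the regulatory T cell list, 25 of which lie above the line of equal signal.

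Foxp3, which drives the GFP used for the sort, served as a check of the labels. Its only probe set gave a signal of 504 in GFP-positive and 173 in GFP-negative cells, a 2.91-fold or 1.54 log2 difference in the direction of the labels. The GFP-negative signal was above the floor, and 3 of the 64 tissue-restricted background genes had at least that signal on the same array.

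Genes known as high in regulatory T cells were higher in GFP-positive cells as a group. Of the 28 members above the floor, 25 were higher and 3 lower, and 9 were at least 2-fold higher. The median difference was 0.95 log2, or 1.93-fold, with quartiles of 0.37 and 1.07, and exceeded the medians of all 10000 matched random lists. The largest differences were those of Gpr83, a G protein-coupled receptor (3.49-fold, signals 1219 and 349), Ecm1, an extracellular matrix protein (3.16-fold, 487 and 154.0), Plagl1, a zinc finger transcription factor (3.04-fold, 356 and 117.0), and Foxp3. Tnfrsf18, which encodes the receptor GITR, was 2.76-fold higher (1394 and 506). Nt5e, which encodes CD73, an enzyme that makes adenosine from AMP, was 2.38-fold higher, and Il10, the gene of an anti-inflammatory cytokine, 2.06-fold. The other members past 2-fold were Ikzf4 (2.11-fold) and Swap70 (2.10-fold), named here after their values were seen. Ikzf2, which encodes Helios, and the inhibitory receptor gene Ctla4 lay just under 2-fold at 1.97-fold (4435 and 2250.3) and 1.94-fold (2419.6 and 1244). Il2ra, which encodes the alpha chain of the IL-2 receptor, was 1.71-fold higher (618 and 362). Other probe sets of these list members, 16 from 11 genes above the floor on both arrays, were all higher in GFP-positive cells. For Ikzf2, Gpr83 and Il2ra they gave 1.77, 1.59 and 0.65 log2. The 3 members that were lower in GFP-positive cells, Ebi3, Klrg1 and Prdm1, also named after their values were seen, differed by −0.15, −0.05 and −0.24 log2.

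**Figure D2:**
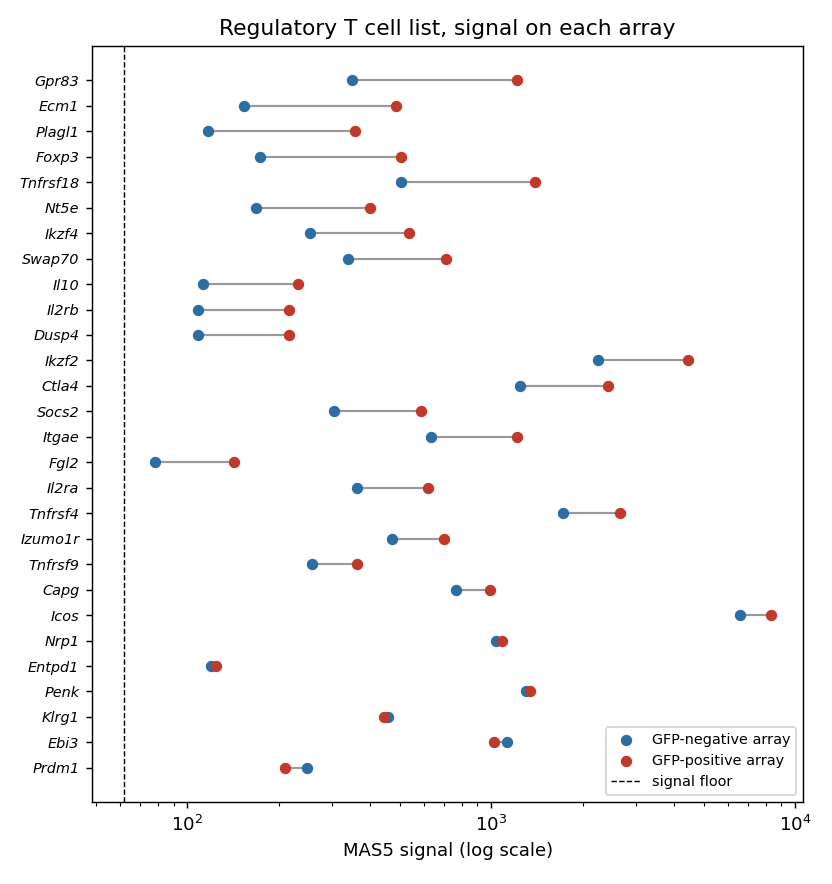
MAS5 signals (x axis, log scale) of the 28 genes of the regulatory T cell list on the GFP-positive (red) and GFP-negative array (blue), ordered by their difference, with the signal floor of 62.05 as a dashed line. All lie above the floor on both arrays, and the difference is widest for Gpr83, with signals of 1219 and 349.

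The largest differences in favour of GFP-positive cells were those of genes outside the lists. Aif1l, an actin-binding protein gene related to Aif1, was 15.8-fold higher in GFP-positive cells (2036.5 and 129), and Itih5, which encodes a heavy chain of the inter-alpha-trypsin inhibitor family, 8.05-fold (1074 and 133). Gsta4, a glutathione S-transferase gene, was 6.88-fold higher and Med18, a subunit of the Mediator complex, 5.76-fold. Psg28 (4.73-fold), Neurl3 (4.01-fold), the T cell receptor gamma variable segment Trgv1 (3.88-fold) and Stap2 (3.71-fold) followed. Among genes with a GFP-negative signal below the floor, Wfdc15a was at least 3.67-fold, Ddx43 at least 3.23-fold, Ddx19b at least 3.10-fold, Aig1 at least 3.08-fold and Gm3715 at least 3.03-fold higher. The second-brightest probe set of Itih5 gave at least 1.92 log2, with a GFP-negative signal below the floor (234.7 and 38.7). Other probe sets of Aif1l had signals of at most 71.3.

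Among genes lower in GFP-positive cells, Efna5, which encodes the Eph receptor ligand ephrin-A5, was at least 6.32-fold lower (21.4 and 392.3) and Cxcr5 at least 5.37-fold lower (29.9 and 333). D630045J12Rik was at least 4.09-fold, Sostdc1, which encodes an antagonist of BMP and Wnt signals, at least 3.19-fold and Dalrd3 at least 3.16-fold lower. Of the genes above the floor on both arrays, Lyst, a regulator of lysosomal traffic, was 3.72-fold lower (128 and 477), Sidt1 3.64-fold, Afg3l1 3.60-fold, Eomes 3.58-fold (80.4 and 288), Csdc2 3.53-fold, Gpatch1 3.49-fold, the ubiquitin ligase gene Pja1 3.46-fold and Tox2 3.22-fold (604 and 1944). A further probe set each of Sostdc1 and Eomes was also lower, at signals of 36.6 and 166 and of 17.8 and 125.0. The further probe set of Sidt1 was above the floor only on the GFP-negative array (60.7 and 72.0), which makes it at least 1.16-fold lower.

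T helper lineage transcription factors were lower in GFP-positive cells in 10 of 13 cases, with a median of −0.26 log2 at percentile 2.11 of random lists. Besides Eomes, which directs cytotoxic and interferon-gamma programmes, the lower members included Bcl6, the follicular helper regulator (203 and 397, 1.95-fold lower), Runx1 (1.80-fold lower) and Stat4, which signals downstream of IL-12 (1137 and 2016, 1.77-fold lower). Irf4, on the activation list as well, was 1.75-fold higher. The probe sets of Runx1 went both ways, and the list median was −0.10 log2 at percentile 20.7 when all probe sets of a gene were averaged.

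Cytokine genes went both ways, with 6 of 13 higher, 7 lower and a median of −0.02 log2 at percentile 44.0. Il10 was the member at least 2-fold higher and Lta was 1.84-fold higher, whereas Tnf was at least 2.24-fold and Ifng, the type 1 helper cytokine, 2.11-fold lower (316 and 667). Il4, named after its values were seen, had signals of 2123 and 1920.5. Without Il10 and Ebi3, which the regulatory T cell list shares, the cytokine median was −0.02 as well. Among chemokine receptors and homing molecules, 6 of 17 were higher and 11 lower, with a median of −0.08 at percentile 29.3. Ccr6, the receptor for CCL20, was 2.47-fold higher (516 and 209), the gut homing receptor gene Gpr15 2.08-fold and the integrin gene Itgae 1.92-fold, opposite to Cxcr5. Without Itgae, which is also on the regulatory T cell list, the median was −0.12.

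Genes of activated and effector T cells were higher in 10 and lower in 10 of 20 cases, with a median of −0.01 log2 at percentile 63.0, which became 0.01 after loess. S100a4, a calcium-binding protein gene of memory and effector cells, was 2.14-fold lower in GFP-positive cells (1456 and 3117), and Cxcr3 was 1.58-fold lower. Without the members of the regulatory T cell list the median was −0.18, at percentile 2.78. Gzmb, named after its values were seen, had similar signals of 1889.5 and 1862. Naive and recirculating T cell genes were lower in 9 of 12 cases, with a median of −0.15 at percentile 12.3 and none past 2-fold. With probe sets averaged their median was −0.23, at percentile 2.62. Bach2, a repressor of effector differentiation, was 1.61-fold lower and Txk 1.35-fold lower, and Klf2, which controls recirculation, was 1.22-fold lower (1833 and 2241).

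Genes known as lower in regulatory T cells had lower signals in 8 of 12 cases, with a median of −0.31 log2 at percentile 0.890. Itgb3 was at least 2.24-fold, Dapl1 2.06-fold and Pde3b, a phosphodiesterase gene, 1.56-fold lower in GFP-positive cells. Il7r, the IL-7 receptor, had signals of 5931 and 7417, or 1.25-fold lower. Igfbp4 went the other way at 1.45-fold higher. With the floor doubled the list lay at percentile 18.7, with probe sets averaged at 3.72, and with the mean in place of the median at 2.59.

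Suppressor effector genes were higher in GFP-positive cells in 10 of 12 cases, with a median of 0.25 log2 at percentile 99.3, and IL-2 and STAT5 signalling genes in 9 of 15 cases, with a median of 0.26 at percentile 99.6. Nt5e, Il10, Ctla4 and Fgl2 (1.82-fold), all on the regulatory T cell list, led the suppressor genes. Il2rb (217 and 108), Socs2 (1.93-fold) and Il2ra, which are on it too, and the STAT5 target gene Cish (1.77-fold, 1136 and 642) led the IL-2 list. The survival genes Mcl1 and Bcl2 differed by 0.06 and −0.07, but further probe sets of Bcl2 went both ways, from −0.24 to 0.74. Without the shared members the suppressor median was 0.06, at percentile 64.9 with 5 genes, and the IL-2 and STAT5 median was −0.0064, at percentile 66.9 with 12 genes. Without a floor the medians of the whole lists were 0.44 and 0.39. After quantile normalization the whole IL-2 and STAT5 list lay at percentile 97.0, and the Il2rb difference was −0.30 log2 when a further probe set below the floor was averaged in.

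TNF receptor family and TRAF genes were higher in 9 and lower in 5 of 14 cases, with a median of 0.06 log2 at percentile 82.1. Tnfrsf18 was the member past 2-fold, Tnfrsf4, which encodes OX40, was 1.53-fold and Tnfrsf25 1.48-fold higher, and Tnfrsf1a was 1.56-fold lower. Co-stimulatory and co-inhibitory receptor genes were higher in 8 and lower in 7 of 15 cases, with a median of 0.10 at percentile 90.7. Pdcd1, the gene of the inhibitory receptor PD-1, was 2.09-fold lower in GFP-positive cells (237 and 494), and Havcr2, which encodes TIM-3, 1.68-fold and Cd86 at least 1.63-fold higher. Without members of the regulatory T cell list the medians were 0.02 and −0.03.

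**Figure D3:**
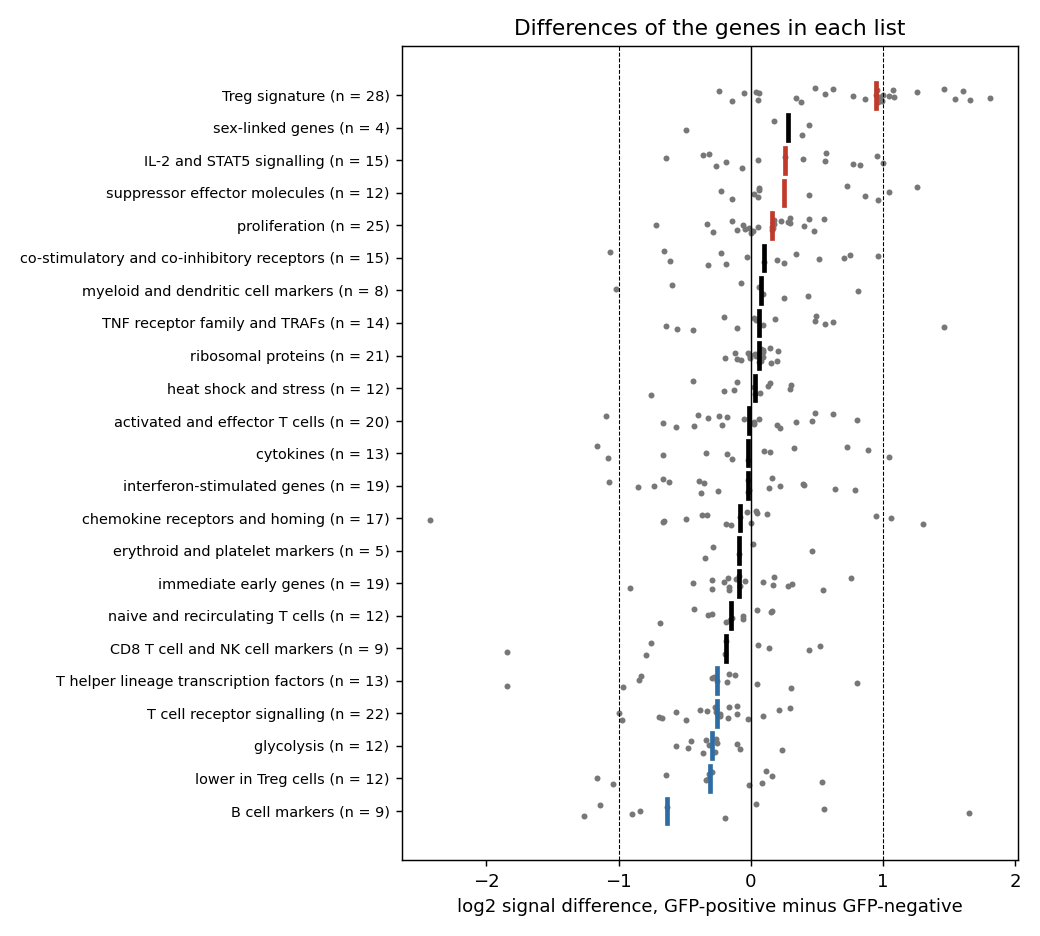
Log2 signal differences (x axis, GFP-positive minus GFP-negative) of the genes above the floor in each of the 23 lists, a point per gene, with the list median as a bar, red in the highest 2.5% and blue in the lowest 2.5% of random lists, and dashed lines at 2-fold. The regulatory T cell list stands furthest to the right with a median of 0.95, and the B cell list furthest to the left with −0.63.

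T cell receptor signalling and glycolysis genes were lower in GFP-positive cells by small amounts. Of 22 receptor signalling genes 19 were lower, with a median of −0.26 log2 at percentile 0.160 and none past 2-fold. Nfatc1, a calcium-dependent transcription factor, had signals of 445 and 889, and its other probe sets were lower too. Cd247, the CD3 zeta chain, was 1.97-fold lower (735 and 1445), but another of its probe sets was higher (183 and 85.9). Cd4 was 1.62-fold and Cd3e 1.59-fold lower, whereas Ptprc, which encodes CD45, was 1.23-fold higher (9329 and 7606), with a further probe set lower (1798 and 2431), and Prkcq was 1.31-fold lower. Of 12 glycolysis genes 11 were lower, with a median of −0.29 at percentile 0.430. Pfkp was 1.48-fold, Pfkl 1.39-fold, the glucose transporter gene Slc2a1 1.37-fold and Aldoa 1.28-fold lower, while the members with the brightest probe sets, Ldha (9182 and 9696) and Pgk1 (5970.0 and 6410.2), were 1.06-fold and 1.07-fold lower. Probe sets of Pfkp, Pfkl and Pgk1 went both ways, and the Pgk1 difference became 0.06 log2 when its probe sets were averaged. With probe sets averaged the receptor signalling list lay at percentile 2.605. The 3′ to 5′ ratio of Gapdh, itself a glycolytic gene, was 9.27 in GFP-positive and 6.24 in GFP-negative cells.

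Proliferation genes were slightly higher in GFP-positive cells, in 17 of 25 cases, with a median of 0.16 log2 at percentile 99.9 and none past 2-fold. Both populations had high signals of cycling genes. Top2a, which encodes a topoisomerase of dividing cells, had signals of 2747 and 2022 (1.36-fold higher), Pcna 8440.5 and 7510.4, Stmn1 6910.4 and 6118, and Mki67, named after its values were seen, 4899.8 and 3987. Tyms was at least 1.47-fold and Bub1 1.39-fold higher and the replication licensing gene Mcm2 1.64-fold lower (289.7 and 475.0). A further probe set of Mcm2 was higher (276.8 and 244.0). The list lay at percentile 96.3 when the mean replaced the median.

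Stress, early response, interferon and ribosomal genes went both ways, with list medians between −0.09 and 0.06 log2. Heat shock and stress genes were higher in 7 of 12 cases, with a median of 0.03 log2 at percentile 79.5. Ddit3 was 1.68-fold and Txnip 1.36-fold lower, Hspd1 and Hsp90aa1 were 1.23-fold higher, and Hspa8 and Hspa5 differed by 0.13 and 0.02. A less bright probe set of Hspa8 gave −1.22. Immediate early genes, which mark recent stimulation, were higher in 7 of 19 cases, with a median of −0.09 at percentile 22.1. Dusp1 was 1.46-fold higher (2920.0 and 2000.2), Fos 1.12-fold higher (2451 and 2186), Dusp5 at least 1.88-fold lower and Ier3 1.35-fold lower, and probe sets of Nr4a2 disagreed. Interferon-stimulated genes were higher in 7 of 19 cases, with a median of −0.02 at percentile 49.5. Oasl2 was at least 2.10-fold, Ifit3 1.81-fold and Irf7 1.66-fold lower, and Gbp3 1.73-fold higher. The interferon median was −0.16 after quantile normalization, −0.13 after loess, −0.19 with probe sets averaged (percentile 3.94) and −0.25 without probe sets that can match several transcripts (percentile 3.26). Ribosomal protein genes were higher in 13 of 21 cases, with a median of 0.06 at percentile 81.9 that became −0.0076 after quantile normalization. Rps20 and Rpl14 differed by 0.20 each, Rpl37 by −0.19, Rpl10a by 0.15, and the brightest, Rpl4 and Rpl22, by 0.09 and −0.08, of which that of Rpl4 turned negative after quantile normalization. The Rpl22 difference became 0.23 with probe sets averaged and 0.46 without probe sets that can match several transcripts.

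B cell markers above the floor were lower in GFP-positive cells in 6 of 9 cases and higher in 3, and the largest difference, that of Cd79b, was in favour of GFP-positive cells. The other 9 of the 18 markers with a probe set were below the floor. The list had a median of −0.63 log2 at percentile 0.025. Ighm, the immunoglobulin heavy chain, was 2.20-fold lower (1881 and 4139), Cd22 2.39-fold lower (98.3 and 235) and Cd74, which serves antigen presentation, 1.86-fold lower, while Cd79b, part of the B cell receptor, was 3.13-fold higher (222 and 70.8). Probe sets of Ighm went both ways, and the Ighm log2 difference became 0.56 when they were averaged, with the list median at −0.20 and percentile 12.2. With the mean in place of the median the list lay at −0.30 and percentile 2.93. Cd79a and Ms4a1, which encodes CD20, named after their values were seen, were below the floor on both arrays.

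Of 23 myeloid and dendritic cell markers 8 were above the floor, 5 higher and 3 lower, with a median of 0.08 log2 at percentile 78.4. The protease gene Ctss was 1.75-fold higher in GFP-positive cells (3879 and 2214.5) and Csf1r at least 1.35-fold, and Fcgr3 was at least 2.03-fold and Mpeg1 1.51-fold lower. Without a floor their median turned to −0.60, at percentile 0.755. Of 15 CD8 T and NK cell markers 9 were above it, 4 higher and 5 lower, with a median of −0.18 at percentile 9.08. Besides Eomes, Ccl5 was 1.73-fold and the cytotoxic granule gene Nkg7 1.69-fold lower (724 and 1222), and Klrd1 was 1.43-fold higher. With the floor doubled these markers lay at −0.76 and percentile 0.030, and without a floor at −0.35 and percentile 2.285. Of 11 erythroid and platelet markers 5 were above it, 2 higher and 3 lower, with a median of −0.09 at percentile 15.5 and signals of at most 102.0. Klf1 was at least 1.37-fold higher, Gp1bb at least 1.27-fold and Pf4 at least 1.22-fold lower, and Itga2b 1.06-fold lower. Their median was −0.26 after quantile normalization and −0.27 after loess, and turned to 0.42 without a floor, at percentile 72.5.

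The 4 sex-linked genes had a median difference of 0.28 log2 at percentile 88.6, which was 0.44 without a floor and 0.85 with probe sets averaged. The Y-linked Eif2s3y had signals of 885 and 678, Kdm5d 76.3 and 107 and Uty 84.1 and 59.6, and Xist, which is expressed from the inactive X chromosome, 69.9 and 23.2.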

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

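The tests of the other probe sets below were chosen after the results were seen.

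Data outside the gene comparison also held signals that differed between the arrays. Among 3565 probe sets above the floor without 1 gene symbol, 95 were at least 2-fold higher and 62 at least 2-fold lower in GFP-positive cells. The 3′ to 5′ ratio of Actb, 5.30 in GFP-positive cells, and that of Gapdh, 9.27, both lay above their values on the GFP-negative array, 3.57 and 6.24, and such controls enter no gene comparison.

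Of the 359 genes past 2-fold, 66 had another probe set above the floor on both arrays, so noise of single probe sets was weighed against differences between the populations. For the regulatory T cell list, 16 of 16 other probe sets, of 11 genes, were higher in GFP-positive cells, with a median of 0.53 log2, which noise without a direction would not give. The 89 other probe sets of those 66 genes had a median of 0.19 log2 in the direction of the call, against 1.195 for all genes past 2-fold, and 61.8% shared the direction. Probe sets below the floor on 1 array were left out, among them some that share the direction of the call, so this median can understate the agreement. Probe set noise may account for single calls, also within the regulatory T cell list, in a share that stays open. The shared direction in that list speaks for the group and not for each gene. Of its 16 other probe sets, 3 were at least 2-fold higher, and Foxp3, Ecm1, Tnfrsf18 and Il10 had only 1 probe set. Differences between animals, sorts or RNA samples stay open, since probe sets of 1 array share them.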

How the results depend on the processing

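The alternative that leaves out members of the regulatory T cell list was chosen after seeing the data. Leaving out arrays in turn was not run, because it would leave a group without an array. Across scalings the counts of genes higher and lower by at least 2-fold ranged from 163 to 181 and from 178 to 202, and no scaling moved the median of all genes by over 0.1 log2. They became 57 and 68 with the floor doubled to 124, 3305 and 2420 without a floor, 925 and 808 at a threshold of 1.5-fold, and 26 and 21 at 3-fold. With a lower floor of 56.5 they were 229 and 203. Averaging the probe sets of a gene gave 219 and 175, of which 85 and 78 were the same genes as in the main analysis. Without a floor, list medians moved to −0.60 for myeloid markers, 0.44 for sex-linked genes, 0.42 for erythroid and platelet markers, which had been negative, −0.04 for heat shock genes, which had been positive, 0.44 for suppressor genes and 0.39 for IL-2 and STAT5 signalling. The last was also 0.39 with the floor of 56.5, and the suppressor value was 0.43 with means in place of medians. Averaging probe sets moved them to −0.10 for T helper transcription factors (percentile 20.7) and 0.85 for sex-linked genes, and the Ighm log2 difference reversed to 0.56. Quantile normalization moved the ribosomal median to −0.0076, and the IL-2 and STAT5 median reversed to −0.0064 without regulatory T cell list members. The cause was not tested in these cases, except that removing the floor admits genes with signals near background. The lists of T cell receptor signalling (2.605), genes lower in regulatory T cells (3.72) and B cells (12.2) left the lowest 2.5% of random lists when probe sets were averaged, and with the floor doubled genes lower in regulatory T cells (18.7) and T helper transcription factors (2.6) did. CD8 T and NK cell markers entered it with the floor doubled (0.030) and without a floor (2.285), as did myeloid markers without a floor (0.755). Means in place of medians took B cell markers (2.93) and genes lower in regulatory T cells (2.59) out of the lowest 2.5% and proliferation (96.3) out of the highest, which IL-2 and STAT5 signalling (97.0) left after quantile normalization. The interferon median ranged from −0.25 without probe sets that can match several transcripts to −0.02. Of 1090 values of named genes other than Foxp3 under alternatives, 1027 moved by less than the probe set spread, 62 by more, and 1 past 2-fold, that of Ighm, reversed. The scalings and the floor of 56.5 moved none by more than that spread, so they add little to this count. The doubled floor moved 27 and averaging probe sets 20. Including smaller differences, 15 values of 14 genes changed sign, 12 of them with probe sets averaged, among them Il2rb (−0.30), Runx1 (0.38), Rps20 (−0.53), Bub1 (−0.16) and Cd247 (0.03). Signal over background limits genes with a signal below 62.05 on 1 array, for which folds are bounds.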

Other observations

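The tests on the GFP-negative signals and on B cells were chosen after the results were seen, as was the selection of Cxcr5, Bcl6, Pdcd1, Tox2 and Sostdc1. The test on further follicular helper genes was fixed before their values were seen.

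Several genes of follicular helper T cells, which help B cells in germinal centres, were lower in GFP-positive cells: Bcl6, Pdcd1 and Tox2, with differences of −0.96, −1.06 and −1.69 log2, and Cxcr5 and Sostdc1, at least 5.37-fold and at least 3.19-fold lower with GFP-positive signals below the floor. A share of follicular helper cells among the GFP-negative cells is a hypothesis for this. Of 11 further genes of these cells 8 were above the floor, 6 of them lower, by the most Sh2d1a (252 and 444), while P2rx7 (475 and 287) and Cd84 (347 and 264) were higher, and their median of −0.11 log2 at percentile 23.4 leaves the hypothesis undecided. B cells in the GFP-negative sample, which the negative selection of CD4+ T cells and the sort at a stated purity of more than 99% would remove, were looked for with 11 B lineage genes, of which 3 were above the floor on the GFP-negative array and likewise 3 on the GFP-positive array. The same 3, Bank1, Cd22 and Cd79b, passed on both arrays. That count decides nothing, since 16 of 64 background genes also lay above the floor on at least 1 array. Of 9 markers of the whole B cell list above the floor, 6 were higher and 3 lower in GFP-negative cells. Ighm (4139 against 1881), Cd74 (424 against 228), H2-Aa and H2-Eb1 were among the higher ones. Cd79b (70.8 against 222) and H2-Ab1 (81.4 against 119.7) were among the lower ones. Probe sets of Ighm went both ways.

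Genes of regulatory T cells also had signals in GFP-negative cells, with Foxp3 at 173, Ctla4 at 1244 and Ikzf2 at 2250.3. GFP-positive cells in the GFP-negative sample, sorted at a stated purity of more than 99%, would need a share of 34.3% to give the Foxp3 signal. That share takes the whole Foxp3 signal as specific. Aif1l allows at most 6.32%, Itih5 12.4%, Gsta4 14.5% and Med18 17.4%. These 4 genes, most with 1 bright probe set, were picked for the largest differences on the same arrays. Picking them so can make the allowed shares too low. The comparison therefore leaves open whether such cells account for the Foxp3 signal. Nonspecific signal as the source for the whole list is argued against by 19 of 28 members above a level, 194, that only the top 2.5% of background genes pass, but it stays open for the other 9, among them Foxp3, whose signal 3 background genes reached. Activated GFP-negative cells stay open too. Activation genes outside the regulatory T cell list went both ways, 7 higher and 8 lower in GFP-positive cells, with a median difference of −0.18 log2. That difference decides nothing, because a comparison of the arrays cannot show activation that both populations share. Cells that express Foxp3 without GFP, and a smaller share of GFP-positive cells, stay open and were not tested.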
